A study of Drosophila melanogaster with 15 samples.

How the data were processed

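RNA-seq was carried out on green fluorescent progenitor cells that were sorted by FACS from elastase-digested midguts of adult Drosophila melanogaster on day 7, per the labels' protocols. RNA was isolated with a PicoPure kit and amplified with a RiboAmp HS PLUS kit before Illumina libraries were made, per the labels' protocols. There were 15 libraries in 5 groups of 3, and each library's group and replicate number came from its title. The groups were wild-type controls (Ctrl), a group labelled with RNAi against ttk (ttk-RNAi), and 3 groups labelled as overexpressing dpn (dpn OE), the intracellular domain of Notch (Nicd OE) or seq together with Nicd (seq&Nicd OE). The labels give no driver line, construct, batch or sorting day. No label says that replicates came from separate flies or sorts, so each p-value measures only the spread between these samples, which may be technical.

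The deposited table held 1 FPKM value per gene and library, normalized by the authors to gene length and to each library's total of reads. Reads were aligned with STAR 2.6.1a to BDGP6 and DESeq2 was used, per the submitters' processing notes. The counting tool, the use of strand and the treatment of overlapping genes were not given in the sources used here. In the table, 63 of 64 protein-coding genes whose exon bases are all shared, with genes of the opposite strand only, were listed at 0 in each library, so reads were assigned without regard to strand. The table listed 17558 genes by identifier, of which 17252 matched a gene of the reference annotation used here, BDGP6.54, and took their symbols from it. The other 306 identifiers stayed in the tests without a name, and the progenitor marker esg was among the symbols that could not be matched. All columns of the table were matched to a library by title.

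Depth was estimated from the low values, because a gene with few reads steps by the FPKM that 1 read is worth. Over genes with up to 20 reads, 97.8% to 98.3% of the values per library were whole numbers of reads within 0.02 reads. The estimated total, in units of 1e6 reads, was 25.1 to 38.4 in Ctrl, 51.1 to 56.0 in ttk-RNAi, 25.9 to 33.4 in dpn OE, 27.0 to 34.1 in Nicd OE and 24.7 to 34.6 in seq&Nicd OE. The share of that total assigned to genes was 56.4% to 62.5% in Ctrl, 62.9% to 65.6% in ttk-RNAi, 60.8% to 63.2% in dpn OE, 33.7% to 48.5% in Nicd OE and 39.6% to 48.9% in seq&Nicd OE. Reads of the 306 identifiers without a match are not counted in this share, as their lengths were not known. For a gene of 1 kb, 1 read was worth 0.018 to 0.041 FPKM and 3 reads 0.054 to 0.122 FPKM. These figures cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

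Values were analysed as log2(FPKM + 1), so a fold change on that scale understates the change of a gene with low values. Genes with FPKM of at least 1 in at least 3 libraries were tested, which left 8209 genes. A gene low in Ctrl could pass this filter through manipulated groups where it is high, which favours a call of a rise there. A linear model with 5 group means was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend, 10 residual degrees of freedom, two-sided). Each manipulated group was compared with Ctrl, and seq&Nicd OE with Nicd OE. The other 5 pairs of manipulated groups were compared in the same fit. Every adjusted p of a gene is limma's, with Benjamini-Hochberg adjustment over the genes of 1 contrast, and genes were called at an adjusted p under 0.05. A fold given beside FPKM is the ratio of the group means. Where the lower group held at most 9 reads in all, a 95% interval was taken from the exact Poisson interval of those reads.

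Gene lists were written before the data were examined and held 387 entries, of which 369 matched the table and 272 were measured, in 16 lists of at least 4 measured members. The lists covered neuroblast identity, temporal factors, proneural factors, neuronal differentiation, enteroendocrine peptides, progenitor markers, Notch targets, digestive genes, cell cycle genes, mitogen and stress signals, immune effectors, heat shock genes and ribosomal proteins. The remaining 3 held markers of other cells, namely visceral muscle, haemocytes with fat body, trachea and glia, and the germline. Each list was tested with fry from limma, with Benjamini-Hochberg adjustment over the 80 tests of 16 lists in 5 contrasts. fry asks whether the members of a list moved, on balance, one way, and does not compare them with other genes. The lists were also tested with camera, with a preset correlation of 0.01 between members and with a correlation estimated from the data. With the estimated correlation 1 of the 46 calls of fry was kept, and that adjusted p stands beside each call. For pairs of manipulated groups camera was run only with the estimated correlation. Members called after adjustment over the list alone are counted beside those called over all genes.

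The genes named in the text were chosen by a rule written before the data were examined. It takes ttk, dpn, seq and N in each library, and 11 marker genes in every contrast whatever their p. It also takes, per contrast, the 6 genes with the largest rise and the 6 with the largest fall among called genes with a group mean of at least 10 FPKM and no overlap between the libraries of the groups. Per list it takes at most the 4 called members with the smallest p. The text names a selection of these. The marker ase was left out by the filter on low values.

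The replicate numbers were checked as a pairing by correlating, across genes, each library's deviations from its group mean. Between Nicd OE and seq&Nicd OE the libraries of the same number correlated at 0.20, 0.21 and 0.43 for replicates 1, 2 and 3, so these numbers were taken to pair the libraries of these groups. The 9 other pairs of groups had at least 1 correlation of 0.02 or less, and their numbers were not read as a pairing. The block by replicate number, with an effect per number common to all 5 groups, was run as an alternative, as written before the data were examined.

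The test was checked on simulated data with 8209 genes of which 200 were changed. Every group was given the Ctrl means and the same spread per gene, taken from the fit of all groups, with normal errors. Of genes changed 2-fold and 4-fold, 56% and 92% were recovered in the simulation of ttk-RNAi, 59% and 91% for dpn OE, 55% and 93% for Nicd OE, 56% and 97% for seq&Nicd OE, and 54% and 95% for seq&Nicd OE against Nicd OE. False calls numbered 6, 7, 8, 8 and 6 in the same order. These simulations differ only by the group changed and the random draw. They follow the assumptions of the model and lack the wider spread of Ctrl and the shifts in scaling between groups, so the rates do not describe the real contrasts.

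Overlaps of calls that share the Ctrl libraries were set beside 100 simulations of unchanged groups and beside the overlap of independent lists, n1 × n2 / N. In each simulation all 15 libraries, those of Ctrl included, were drawn from the Ctrl means with a spread per gene pooled over the 5 groups. For Nicd OE and seq&Nicd OE the 100 simulations were run again with deviations correlated by replicate number as measured. Alternatives covered the pseudocount, the filter, the scaling of the libraries, the libraries in the fit, the replicate block, weights per library, the variance trend, a minimum fold change and leaving out each library in turn. Chosen after seeing the data were equal assigned reads, median-of-ratios scaling, median scaling for lists, overlaps and pairs of manipulated groups, camera for those pairs, and the simulation correlated by replicate number. Weights per library used limma's gene-by-gene method, chosen after the default method had stopped before it converged, with a weight of 0 for 1 library. The scaling matters to directions here, because the median log2 change of all genes was 0.24 in ttk-RNAi, 0.50 in dpn OE, -0.40 in Nicd OE and -0.17 in seq&Nicd OE against Ctrl, and 0.22 in seq&Nicd OE against Nicd OE. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.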

Results

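The data are FPKM values of RNA from sorted midgut progenitor cells of adult flies, in 15 libraries that fall into 5 groups of 3. The groups are wild-type controls (Ctrl) and libraries labelled ttk-RNAi, dpn OE, Nicd OE and seq&Nicd OE, where OE stands for overexpression and Nicd for the intracellular domain of Notch. Between 5563 and 7300 genes per library had an FPKM of at least 1. Levels below are group means in FPKM ± SD with n = 3 libraries per group, and folds are ratios of these means, given again without a library where that library alone moved a fold by over 1.5 times. Where the lower group held at most 9 reads in all, the 95% counting interval of the fold follows it, which is exact (Poisson), taken from those reads alone, and covers counting error only. The largest rises and falls are instead ranked on log2(FPKM + 1), among called genes with a group mean of at least 10 FPKM and no overlap between the libraries of both groups. Correlations across genes between libraries of 1 group were 0.91 to 0.97 in Ctrl and 0.97 to 1 in the other groups, and Ctrl replicate 2 had the lowest, with a mean of 0.92. The first 3 principal components held 37.9%, 32.3% and 11.2% of the variance. Counts of list members adjusted over the list alone are given where they differ from those over all genes tested, and the splits of rises and falls are relative to the deposited FPKM unless another scaling is named.

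The genes named in the labels were read first, as a check of the labels. The gene ttk (FBgn0003870, BDGP6.54 3R:31713867-31735392), which encodes the zinc-finger repressor Tramtrack, was higher in libraries labelled ttk-RNAi than in Ctrl, at 100 ± 12.9 against 30.2 ± 17.0. That difference of 3.31-fold (adjusted p = 0.00089) is a rise where the label names RNAi. Reads from an RNAi construct, a rise of the endogenous transcript and a wrong label cannot be told apart here, and the libraries are called by their label throughout. The gene was at 20.5 ± 4.08 in dpn OE, 14.1 ± 4.38 in Nicd OE and 20.3 ± 3.71 in seq&Nicd OE, none of them called against Ctrl (adjusted p = 0.45, 0.077 and 0.49). Without Ctrl replicate 2, which had the lowest ttk of the controls, all 3 fell (adjusted p = 0.006, 0.00044 and 0.0081), and ttk in Nicd OE also fell without Nicd OE replicate 3 (adjusted p = 0.044). In dpn OE ttk also fell under median scaling (adjusted p = 0.013).

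The gene dpn (FBgn0010109, 2R:8228971-8232330), which encodes the neuroblast transcription factor Deadpan, was at 2.37 ± 0.803 in Ctrl and 6.09 ± 1.30 in libraries labelled dpn OE, 2.57-fold higher (adjusted p = 0.0082). That call was lost with median scaling (adjusted p = 0.053) and quantile normalization (0.071). It was far higher in libraries labelled ttk-RNAi, at 290 ± 21.6, and seq&Nicd OE, at 225 ± 65.6, and was at 1.98 ± 1.34 in Nicd OE. Of its exon bases 59.3% are shared with the antisense gene asRNA:CR44275, and its values are uncertain. Of 64 protein-coding genes whose exon bases are all shared, with genes of the opposite strand only, 63 (98.4%) were listed at 0 in each library, against 2.9% of those sharing none. The gene seq (FBgn0028991, 2R:13176553-13190086), which encodes the zinc-finger factor Sequoia, was listed at 0 in each of the 15 libraries, those labelled seq&Nicd OE included. All of its exon bases are shared with CG17724 and Kdm4B, so the table holds no check of that label. The gene N (FBgn0004647, X:3134870-3172221), which encodes the Notch receptor, was at 63.0 ± 18.5 in Ctrl and lower in libraries labelled Nicd OE (21.8 ± 6.39, adjusted p = 0.0012) and seq&Nicd OE (18.3 ± 5.47, adjusted p = 0.00027). A rise from an Nicd transgene is therefore not seen in these values. It was 30.0 ± 2.41 in ttk-RNAi (adjusted p = 0.011) and 38.6 ± 7.29 in dpn OE (adjusted p = 0.062, but 0.0098 without Ctrl replicate 2 and 0.00037 with median scaling).

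**Figure D1:**
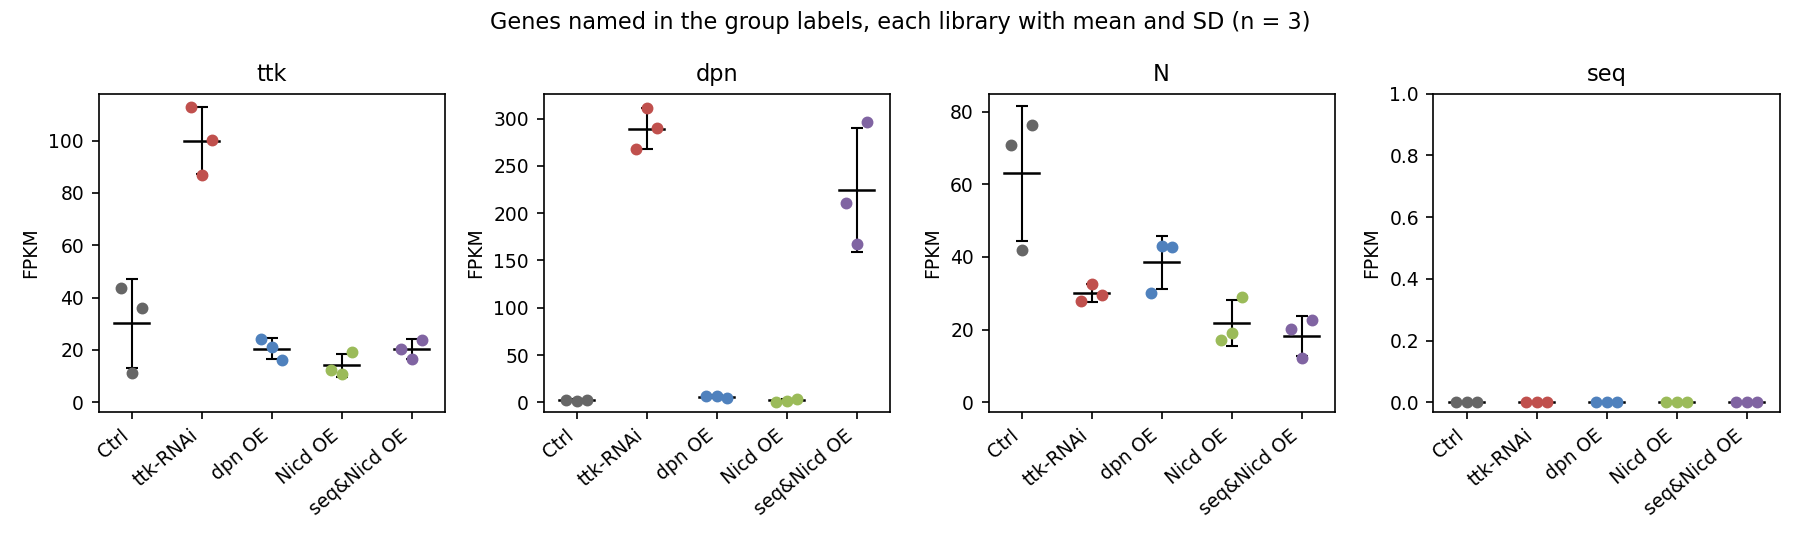
FPKM of ttk, dpn, N and seq in each library (points) by group, with the group mean and SD (n = 3, linear axes). The libraries labelled ttk-RNAi held the highest ttk, at 100 ± 12.9, dpn was highest in ttk-RNAi and seq&Nicd OE, and seq was listed at 0 in each library.

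Libraries labelled ttk-RNAi were compared with Ctrl to ask what progenitors express when ttk is targeted. The zinc-finger factor gene sna (FBgn0003448, 2L:15476593-15478260), on the list of progenitor markers, rose 85-fold, from 6.72 ± 2.29 to 571 ± 89.9, and its relative wor, on the neuroblast list, rose 23-fold, from 1.24 ± 0.461 to 28.5 ± 2.11. Beside them dpn rose 122-fold and chinmo, which encodes a timing factor of neural progenitors, rose 266-fold, from 0.282 ± 0.0279 to 75.2 ± 4.74. The gut hormone gene NPF fell 74.8-fold, from 29630 ± 24770 to 396 ± 18.2 (41.5-fold without Ctrl replicate 2), and Orcokinin fell 28-fold, from 2831 ± 174 to 101 ± 23.1. The cell cycle genes CycE (cyclin E) and stg (the Cdc25 phosphatase String) rose 13.5-fold and 3.3-fold, to 8.79 ± 0.661 and 88.5 ± 8.31.

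On log2(FPKM + 1), the largest rises were in Listericin (FBgn0033593, 2R:11241745-11242194), an antibacterial protein gene, at 3336 ± 618.5 against 2.13 ± 1.18 (1570-fold), and in CG13460, at 1136 ± 20.8 against 0.475 ± 0.159. Idgf4, a chitinase-like growth factor gene, reached 140 ± 5.60 from 0.0452 ± 0.0429 (3090-fold, interval 1630 to 6760, or 5550-fold without Ctrl replicate 1), and 2 long non-coding RNAs, lncRNA:CR30009 and lncRNA:CR44272, rose 327-fold and 140-fold. The largest falls on that scale were in NPF, E(spl)m3-HLH (47-fold), CG10479 (47.9-fold), Orcokinin, E(spl)malpha-BFM (29.3-fold) and the cytochrome P450 gene Cyp4p2 (457-fold). Adjusted p for these 11 genes was 1.8e-07 or lower.

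The neuroblast list held 20 measured genes, of which 9 rose, 4 fell and 7 did not pass, and the list rose (fry adjusted p = 0.00021, adjusted p = 0.9 with an estimated correlation). Adjusted over the list alone, 10 rose and 4 fell. Members that rose included scrt (13.6-fold) and klu (3.43-fold), which encode zinc-finger factors, while the RNA regulator lin-28 fell 4.15-fold and insc, a gene of asymmetric division, fell 2.36-fold. The markers mira and pros were at 19.9 ± 2.36 and 8.08 ± 0.45 against 16.4 ± 8.24 and 8.88 ± 2.21 in Ctrl, without a call (adjusted p = 0.42 and 0.71). Of 17 neuronal differentiation genes, 10 rose, 1 fell and 6 did not pass (fry adjusted p = 0.00086, 0.71 with an estimated correlation, and 0.052 with median scaling, where 6 rose and 1 fell). Among these Appl, the fly homologue of the amyloid precursor protein, rose 7.39-fold to 132 ± 8.90, and the vesicle release genes Snap25 and Cadps rose 9.96-fold and 5.75-fold. The pan-neuronal marker elav was at 8.30 ± 0.319 against 6.97 ± 2.27 (adjusted p = 0.38).

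Of 17 enteroendocrine genes, 3 rose, 9 fell and 5 did not pass, with 4 rising adjusted over the list alone (fry adjusted p = 0.00067, 0.58 with an estimated correlation). The prohormone convertase gene amon fell 20.4-fold to 2.86 ± 0.373, while Syt4, a synaptotagmin gene, rose 26-fold to 46.1 ± 1.53 (49.7-fold without Ctrl replicate 3). The 11 Notch targets fell as a list, with 3 up and 5 down (6 down adjusted over the list alone, fry adjusted p = 0.011, 0.65 with an estimated correlation, and 0.079 without Ctrl replicate 2). With median scaling 2 were up and 6 down. They moved apart: E(spl)mgamma-HLH rose 23.6-fold to 128 ± 5.76, and E(spl)mbeta-HLH fell 13-fold to 51.1 ± 3.52. E(spl)m8-HLH was at 19.4 ± 0.981 against 13.2 ± 5.91 (adjusted p = 0.098, or 0.0069 without Ctrl replicate 2), and the Notch ligand gene Delta fell 17-fold to 4.41 ± 0.576 (7.17-fold without Ctrl replicate 1). Digestive genes fell, 11 of 29 against 2 that rose, or 17 against 2 with median scaling (fry adjusted p = 0.0087, 0.44 with an estimated correlation), with the trypsin gene alphaTry 8.45-fold lower (14.1-fold without ttk-RNAi replicate 3) and the protease gene Jon65Aiii 5.17-fold lower. Cell cycle genes rose, 12 of 29 with none lower (fry adjusted p = 0.016, 0.8 with an estimated correlation), as RnrS, the small subunit of ribonucleotide reductase, did (5.85-fold).

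Of 10 heat shock genes 5 fell, or 8 with median scaling, and none rose (fry adjusted p = 0.023, 0.59 with an estimated correlation), such as Hsp68 (3.73-fold) and DnaJ-1 (3.12-fold). The germline list rose with 4 of 4 members (fry adjusted p = 4.9e-05, 0.58 with an estimated correlation), piwi at 2.48 ± 0.333 against 0.157 ± 0.0661 and AGO3 4.37-fold higher, both of the piRNA pathway. The list of haemocyte, fat body, trachea and glia markers rose with 2 of 6 (fry adjusted p = 4.9e-05, 0.58 with an estimated correlation), led by the chitin deacetylase gene verm, 161-fold higher at 10.4 ± 0.499. Only 2 of the 4 germline genes and 2 of these 6 markers had a mean of at least 1 FPKM in Ctrl. The others needed manipulated libraries to pass the filter, which favours a rise over Ctrl. Immune effectors rose with 3 of 7 (fry adjusted p = 0.0026, 0.8 with an estimated correlation), a call lost with median scaling (0.22) and quantile normalization (0.11).

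Lists without a call were the progenitor markers (4 of 12 up and 2 down, 3 down adjusted over the list alone, fry adjusted p = 0.063, but called up at 0.043 with equal assigned reads) and mitogen and stress signals (3 of 13 up, 5 down, 0.85). Temporal factors were without a call as well (2 of 5 up, 1 down, or 2 and 2 with median scaling, 0.57, with a median log2 change of 0.20 and a mean of -0.20). Of the mitogen list, the cytokine gene upd3 and the protease gene rho rose 3.9-fold and 3.49-fold. Also uncalled were visceral muscle markers (2 of 4 up, 2 down, or 1 and 2 with median scaling, 0.61), ribosomal proteins (4 of 79 up, 24 down, 21 adjusted over the list alone, 0.13) and proneural factors (2 of 9 up, 4 down, 0.66). The ribosomal list was called down with median scaling (0.04, 1 up and 36 down), quantile normalization (0.012) and by camera with the preset correlation (6.1e-07). Proneural factors were called down with median scaling (0.0081, 1 up and 5 down) and quantile normalization (0.0032). One proneural member, the bHLH gene tap, fell 26.4-fold to 1.53 ± 0.189 (17.4-fold without Ctrl replicate 2).

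In all 3638 of 8209 genes changed, 2517 up and 1121 down (limma, Benjamini-Hochberg adjusted p under 0.05), that is 69.2% up. The split was 1950 up and 2209 down with median scaling and 2025 and 2119 with quantile normalization. It was 2389 and 1346 with equal assigned reads and 2222 and 1750 with median-of-ratios scaling, so which direction prevailed rests on the scaling.

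**Figure D2:**
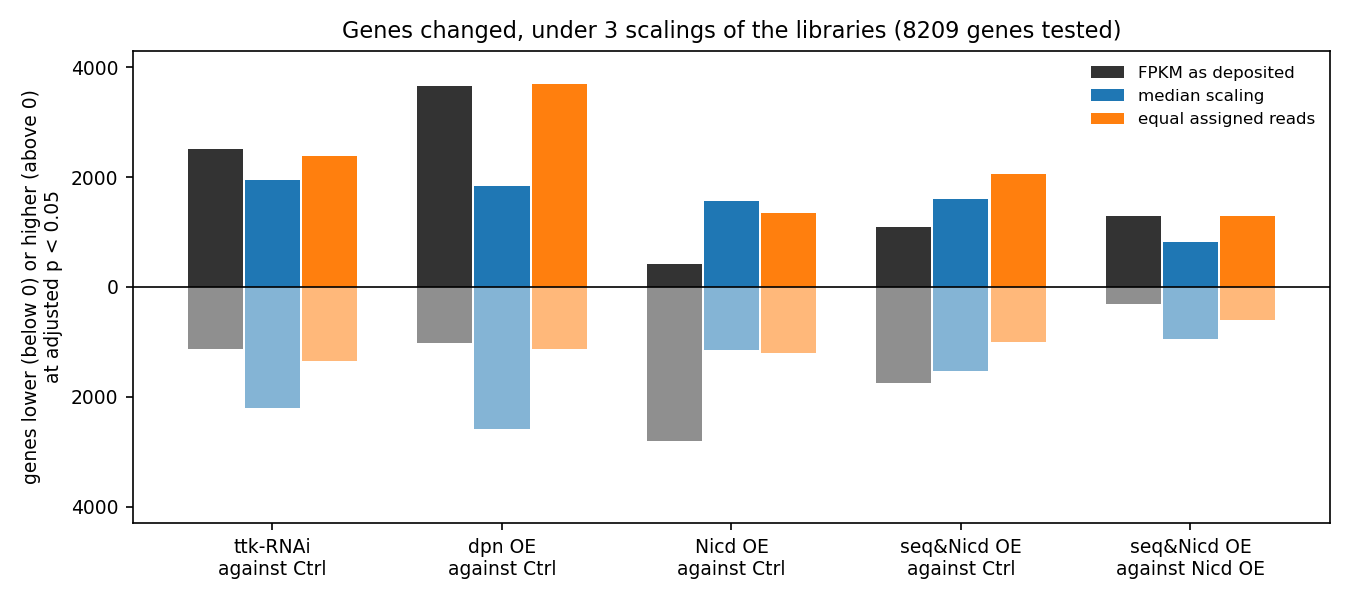
Number of genes higher (above 0) and lower (below 0) at an adjusted p under 0.05 in each comparison, of 8209 tested, with FPKM as deposited, median scaling and equal assigned reads. In Nicd OE against Ctrl 416 genes were higher with FPKM as deposited and 1566 with median scaling.

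Libraries labelled dpn OE were compared with Ctrl to ask what overexpressed dpn changes in progenitors. The hormone gene Tk (tachykinin) fell 22.7-fold, from 1561 ± 1098 to 68.8 ± 5.65 (14.1-fold without Ctrl replicate 3), and IA-2, a gene of dense-core vesicles, fell 23.7-fold, from 332 ± 206 to 14.0 ± 2.19. The homeobox factor gene pros (Prospero) fell 15.9-fold, from 8.88 ± 2.21 to 0.56 ± 0.0591, and nSyb (neuronal synaptobrevin) 12.9-fold. On the cell cycle list, pav (a kinesin of cytokinesis) rose 7.53-fold, from 0.895 ± 0.761 to 6.74 ± 1.06, and the checkpoint kinase gene BubR1 4.87-fold (14.8-fold and 9.13-fold without Ctrl replicate 1). The phosphatase gene stg of the same list, added here after its values were seen, fell 2.25-fold (adjusted p = 0.0015). Diedel (FBgn0039666, 3R:29493852-29494267), a secreted immune regulator gene, rose from 0.0873 ± 0.0947 to 118 ± 18.9. With 4 reads in the 3 Ctrl libraries this was 1350-fold with an interval of 529 to 4970 (3190-fold without Ctrl replicate 1).

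After Diedel, the largest rises on log2(FPKM + 1) were in CG33109 (54.3 ± 32.2 against 3.23 ± 5.04, 16.8-fold), 28SrRNA-Psi:CR45853 (116-fold, interval 39.6 to 562), lncRNA:CR45156 (36.4-fold), CG18765 (37.8-fold) and CG2082 (35.1-fold). Without Ctrl replicate 2 the first 2 folds were 164 and 277. The largest falls on that scale were in lncRNA:CR45378, at 0.0547 ± 0.0216 against 33.9 ± 23.9 (6 reads in dpn OE, 621-fold, interval 285 to 1690, or 369-fold without Ctrl replicate 2), and Nap1, a histone chaperone gene, at 0.306 ± 0.112 against 30.9 ± 7.15. These 2 genes share 42.0% and 73.0% of their exon bases with other genes, so their values are uncertain. Both were also low in replicates 1 and 2 of Nicd OE (0.143 and 0.0890 for lncRNA:CR45378, 0.272 and 0.305 for Nap1) and of seq&Nicd OE (0.171 and 0.130, 0.180 and 0.179), but not in replicate 3 of either (31.1 and 29.1, 26.5 and 19.1). The sodium pump subunit gene nrv3 fell 17.9-fold and lncRNA:CR44272 fell 120-fold (interval 54.9 to 326).

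Of 9 proneural factors 8 fell and none rose, with a median log2 change of -2.00 (fry adjusted p = 1.6e-07). This is the one call in the 5 comparisons that was kept by camera, with adjusted p = 0.048 with an estimated correlation. Among them phyl, tap and mirr fell 94.1-fold, 15.7-fold and 7.48-fold, from Ctrl levels of 3.27 ± 1.06, 40.5 ± 24.5 and 6.90 ± 2.22. The fold of phyl had an interval of 40.3 to 290 and was 158 without dpn OE replicate 1, and that of tap 10.3 without Ctrl replicate 2. Of 17 neuronal genes 12 fell (13 adjusted over the list alone) and none rose (fry adjusted p = 2.8e-05, 0.15 with an estimated correlation), with Syt1 18.8-fold and Appl 8.62-fold lower. Of 17 enteroendocrine genes 13 fell and none rose (fry adjusted p = 3.8e-05, 0.18 with an estimated correlation), Syt7 by 31.1-fold and Orcokinin by 7.15-fold, to 396 ± 84.4. Of 11 Notch targets 7 fell, or 11 with median scaling, and none rose (fry adjusted p = 6.8e-06, 0.15 with an estimated correlation), such as E(spl)m7-HLH (20.6-fold) and E(spl)m8-HLH (46-fold, to 0.286 ± 0.0316). E(spl)mbeta-HLH was at 459 ± 51.0 against 662 ± 329 (adjusted p = 0.18, or 0.0025 with median scaling). Of 5 temporal factors 3 fell (4 adjusted over the list alone, 5 with median scaling) and none rose (fry adjusted p = 0.00067, 0.34 with an estimated correlation).

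Of 29 cell cycle genes 22 rose and 2 fell (fry adjusted p = 0.01, 0.83 with an estimated correlation). This call was lost with median scaling (0.096, 13 up and 4 down) and quantile normalization (0.052), although the call of Ndc80, a kinetochore gene 4.39-fold higher (9.45-fold without Ctrl replicate 1), held with both. Of 79 ribosomal protein genes 35 rose and none fell, 34 adjusted over the list alone (fry adjusted p = 0.041, 0.96 with an estimated correlation), a call lost with median scaling (0.99, 10 up and 10 down) and equal assigned reads (0.057). The germline list rose with 2 of 4 (fry adjusted p = 0.016, 0.96 with an estimated correlation), but was lost without Ctrl replicate 2 (0.13), and its direction turned with median scaling (0.63, down, with 1 up and 1 down).

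The neuroblast list was not called, with 5 of 20 up and 6 down (fry adjusted p = 0.42), but it was called down with median scaling (2.2e-05, 2 up and 11 down), quantile normalization (4.1e-05), without Ctrl replicate 2 (0.035) and by camera with the preset correlation (0.039). Its members pins and Galphai, of the spindle orientation machinery, rose 2.78-fold and 2.85-fold. The marker mira was at 31.1 ± 10.5 against 16.4 ± 8.24 (adjusted p = 0.036), a call lost without dpn OE replicate 1 (0.11) or 2 (0.14), without Ctrl replicate 2 (0.072) or 3 (0.17), and with median scaling (0.35). A fall of wor, to 0.456 ± 0.0138 (adjusted p = 0.024), was lost without dpn OE replicate 1, 2 or 3 (0.062, 0.067 and 0.051) or Ctrl replicate 1 or 3 (0.057 and 0.1). Levels of insc were 30.6 ± 3.34 against 41.0 ± 1.62 and of elav 5.45 ± 0.335 against 6.97 ± 2.27 (adjusted p = 0.13 and 0.35). Both were called down with median scaling (0.0024 and 0.00046), and elav without Ctrl replicate 2 (0.045). Delta was at 134 ± 26.0 against 74.9 ± 76.8 (adjusted p = 0.051, or 0.048 with equal assigned reads and 0.00066 without Ctrl replicate 1).

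Other lists without a call were the progenitor markers (2 of 12 up and 5 down, 3 up and 6 down adjusted over the list alone, fry adjusted p = 0.58), mitogen and stress signals (4 of 13 down, 3 adjusted over the list alone, 0.37, median log2 change 0.05 and mean -0.34, with the Fos gene kay 7.43-fold lower), visceral muscle (1 of 4 down, 0.24) and haemocyte, fat body, trachea and glia markers (1 of 6 up, 1 down, 0.45). These 4 lists were called down with median scaling (0.00067, 0.0014, 3.6e-05 and 0.0047), with 1, 0, 0 and 0 members up and 6, 6, 2 and 2 down. The muscle list was also called without Ctrl replicate 2 (0.027), and the mitogen list by camera with the preset correlation (0.029). Digestive genes (8 of 29 up and 1 down, 7 up adjusted over the list alone, 4 up and 3 down with median scaling, 0.071), immune effectors (1 of 7 up, 2 down, 0.81, median -0.02 and mean 0.02) and heat shock genes (1 of 10 up, 2 down, or 1 and 4 with median scaling, 0.9) were uncalled as well.

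In all 4686 genes changed, 3658 up and 1028 down, or 78.1% up (limma, Benjamini-Hochberg). With median scaling 1845 rose and 2581 fell, with quantile normalization 2274 and 1711, with equal assigned reads 3687 and 1133, and with median-of-ratios scaling 2316 and 1783.

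Libraries labelled Nicd OE were compared with Ctrl to ask what an active Notch fragment changes. The cytokine gene upd2 fell 150-fold, from 141 ± 105 to 0.941 ± 0.614 (86.7-fold without Ctrl replicate 1, 240-fold without Nicd OE replicate 3), and the JAK/STAT feedback gene Socs36E 6-fold, from 315 ± 140 to 52.5 ± 10.3. The heat shock gene Hsp68 fell 40.2-fold, from 134 ± 42.5 to 3.33 ± 0.728, and stg fell 10.3-fold, from 26.9 ± 5.79 to 2.62 ± 1.27. The Notch target E(spl)mgamma-HLH rose 12.2-fold, from 5.40 ± 1.53 to 66.0 ± 8.67, while E(spl)mbeta-HLH fell 4.57-fold and E(spl)m8-HLH 18.7-fold, to 145 ± 13.8 and 0.703 ± 0.692 (42.5-fold for E(spl)m8-HLH without Nicd OE replicate 3). These libraries also had low shares of reads assigned to genes, 33.7% to 48.5% against 56.4% to 62.5% in Ctrl.

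The largest rises on log2(FPKM + 1) were in CG6006 (FBgn0063649, 3R:16154982-16171766, 35.2-fold, to 130 ± 38.3), lncRNA:CR44538 (30.4-fold), CG15629 (108-fold), CG10433 (31.4-fold) and Irc, a catalase gene of gut immunity (47.6-fold, to 17.9 ± 3.51). Shared exon bases make up 13.2% of CG15629 and 20.8% of CG10433. The largest falls on that scale were in CG45061 (178-fold, from 850 ± 444), CG45060 (95.8-fold, from 612 ± 198), upd2, Hsp68 and NPF (31.6-fold, to 937 ± 337, or 17.5-fold without Ctrl replicate 2). Without Nicd OE replicate 3 the folds of CG45061 and CG45060 were 278 and 215.

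Of 13 mitogen and stress genes 12 fell and none rose (fry adjusted p = 0.00011, 0.58 with an estimated correlation), including Ets21C (5.65-fold, or 9.34-fold without Nicd OE replicate 3, 28.3% of exon bases shared) and the phosphatase gene puc (4.54-fold). Of 10 heat shock genes 8 fell and none rose (fry adjusted p = 0.00035, 0.62 with an estimated correlation), with Hsp23 and Hsp26 23.1-fold and 22.2-fold lower from 1406 ± 581 and 1585 ± 558. Of 9 proneural factors 9 fell (fry adjusted p = 1.1e-07, 0.11 with an estimated correlation), sc (scute) from 7.31 ± 4.67 to 0.0746 ± 0.0415 (98.0-fold, or 63.4-fold without Ctrl replicate 1) and tap 16.2-fold (10.7-fold without Ctrl replicate 2). Of 20 neuroblast genes 11 fell, 13 adjusted over the list alone, and none rose (fry adjusted p = 0.00035, 0.65 with an estimated correlation), such as lin-28 (4.78-fold), loco (4.84-fold, 13.5% of exon bases shared), insc (4.83-fold) and mira (5.31-fold). The marker wor was at 0.564 ± 0.268 against 1.24 ± 0.461 (adjusted p = 0.067, or 0.011 without Ctrl replicate 2 and 0.03 without Nicd OE replicate 3). Of 12 progenitor markers 9 fell, 10 adjusted over the list alone, and none rose (fry adjusted p = 0.0014, 0.65 with an estimated correlation), sna by 5.98-fold, and Delta by 26.9-fold to 2.79 ± 2.25. Without Nicd OE replicate 3 these folds were 10.8 and 49.8, and that of Delta was 11.3 without Ctrl replicate 1. Of 29 cell cycle genes 17 fell, 18 adjusted over the list alone, and none rose, or 11 fell and 1 rose with median scaling (fry adjusted p = 0.016, 0.83 with an estimated correlation, 0.057 with equal assigned reads), Cdk1 by 7.71-fold.

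The calls of 5 other lists were lost under other scalings. Of 17 neuronal genes 14 fell, 15 adjusted over the list alone (fry adjusted p = 0.00067, 0.65 with an estimated correlation). That call was lost with median scaling (0.16, 1 up and 3 down) and quantile normalization (0.067), though the calls of its member Syt1 (4.63-fold lower) and of pros (5.55-fold lower) held with both. The neuronal marker elav fell 2.42-fold to 2.88 ± 0.97 (adjusted p = 0.0033, or 0.065 with equal assigned reads). Of 17 enteroendocrine genes 2 rose and 12 fell, 13 adjusted over the list alone (fry adjusted p = 0.0016, 0.71 with an estimated correlation), such as amon (4.23-fold), but not with median scaling (0.073), equal assigned reads (0.057) or quantile normalization (0.052). Of 11 Notch targets 1 rose and 5 fell (fry adjusted p = 0.0029, 0.93 with an estimated correlation), E(spl)malpha-BFM by 13.2-fold, and this call too was lost with each of these scalings (0.48, 0.71 and 0.42), with 2 up and 4 down under the first. Of 79 ribosomal genes 33 fell, 36 adjusted over the list alone (fry adjusted p = 0.028, 0.91 with an estimated correlation). That call was lost with median scaling (0.69, 4 up and 3 down), quantile normalization (0.94) and without Ctrl replicate 2 (0.1), and its direction turned with equal assigned reads (0.97, up). The haemocyte, fat body, trachea and glia list fell with 1 of 6 (fry adjusted p = 0.04, 0.98 with an estimated correlation), but not with the same 3 scalings (0.95, 0.27 and 0.23).

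Lists without a call were the temporal factors (2 of 5 down, 1 with median scaling, fry adjusted p = 0.05, but called at 0.0027 without Ctrl replicate 2), digestive genes (3 of 29 up, 2 adjusted over the list alone, 7 with median scaling, 0.61, but 0.0006 by camera with the preset correlation) and immune effectors (0 of 7, 0.15). Visceral muscle markers were uncalled too (1 of 4 up, 1 down, 0.12, but 0.021 without Ctrl replicate 2). The germline list was uncalled (1 of 4 up, none adjusted over the list alone, 0.91, median log2 change -0.07 and mean 0.17), but was called up with median scaling (0.00067) and quantile normalization (0.032). A digestive protease gene, Jon74E, rose 12-fold to 30.9 ± 12.9.

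In all 3227 genes changed, 416 up and 2811 down, or 12.9% up (limma, Benjamini-Hochberg), and 2151 without Nicd OE replicate 1, 389 up and 1762 down. With only Nicd OE and Ctrl in the fit 1512 changed, 195 up and 1317 down. With median scaling 1566 rose and 1148 fell, with quantile normalization 1474 and 1380, with equal assigned reads 1353 and 1208, and with median-of-ratios scaling 1125 and 1940.

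Libraries labelled seq&Nicd OE were compared with Ctrl to ask what seq changes together with Nicd. The gene stai (the tubulin-binding stathmin, FBgn0266521, 2L:6100377-6124653) rose 64.4-fold, from 3.42 ± 1.21 to 220 ± 7.62, sna rose 56.2-fold, to 378 ± 22.2, and wor 41.8-fold, to 51.8 ± 9.74. The Notch targets E(spl)mgamma-HLH and E(spl)m8-HLH rose 51.4-fold and 4.76-fold, to 278 ± 13.5 and 62.8 ± 0.753, and dpn rose 94.9-fold. The gut hormone genes CCHa1 and CCHa2 rose 9.63-fold and 7.95-fold, to 142 ± 37.3 and 140 ± 86.5 (5.17-fold for CCHa2 without seq&Nicd OE replicate 2), while Orcokinin fell 3.9-fold to 726 ± 78.3. Hsp68 and upd2 fell 18.4-fold and 35.5-fold, to 7.27 ± 0.833 and 3.97 ± 2.16 (20.5-fold for upd2 without Ctrl replicate 1). The share of reads assigned to genes was low here as well, at 39.6% to 48.9%.

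The long non-coding RNAs lncRNA:CR30009 and lncRNA:CR44272 had the largest rises on log2(FPKM + 1), to 2166 ± 491 and 2240 ± 586, followed by CG13460 (164 ± 181, 346-fold, or 127-fold without seq&Nicd OE replicate 3). The largest falls on that scale were in CG45060 (54.4-fold, or 96.9-fold without seq&Nicd OE replicate 3), CG6357 (57.7-fold, to 8.16 ± 0.719), CG45061 (26.7-fold), E(spl)malpha-BFM (26.9-fold), upd2 and E(spl)m3-HLH (21.1-fold).

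Of 17 neuronal differentiation genes 13 rose and 1 fell (fry adjusted p = 3.8e-05, 0.33 with an estimated correlation), such as Appl (7.81-fold, to 139 ± 43.0), Snap25 (10.7-fold), Cadps (8.7-fold) and fne, an elav relative (8.75-fold). Of 11 Notch targets 6 rose and 3 fell, 4 adjusted over the list alone, with a median log2 change of 0.70 and a mean of -0.05 (fry adjusted p = 0.0072, up, 0.71 with an estimated correlation, 0.22 with median scaling). The Brd-family gene Tom rose 28.3-fold (interval 13 to 77.2) and E(spl)mbeta-HLH fell 9.01-fold. The germline list rose with 3 of 4 (fry adjusted p = 0.00088, 0.44 with an estimated correlation), piwi 11.6-fold (7.51-fold without seq&Nicd OE replicate 3). Only 2 of these 4 genes had a mean of at least 1 FPKM in Ctrl, so the filter favours a rise here as well.

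Of 13 mitogen and stress genes 9 fell, 11 adjusted over the list alone, and none rose (fry adjusted p = 0.00056, 0.58 with an estimated correlation), kay by 9.55-fold, Socs36E by 5.38-fold and puc by 4.69-fold. Of 10 heat shock genes 7 fell, 8 adjusted over the list alone, and none rose (fry adjusted p = 0.00087, 0.58 with an estimated correlation), such as Hsp26 (12.3-fold). Of 9 proneural factors 1 rose and 4 fell (fry adjusted p = 0.01, down, 0.65 with an estimated correlation, 0.4 with equal assigned reads). There scrt rose 12.5-fold and tap fell 27.9-fold (18.4-fold without Ctrl replicate 2). Of 79 ribosomal genes 1 rose and 35 fell, 37 adjusted over the list alone (fry adjusted p = 0.028, 0.71 with an estimated correlation). That call was lost with median scaling (0.16, none up and 19 down), equal assigned reads (0.51) and quantile normalization (0.38), and without Ctrl replicate 2 (0.091).

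The neuroblast list was not called, with 4 of 20 up and 8 down, a median log2 change of -0.38 and a mean of 0.14 (fry adjusted p = 0.37), but it was called up with median scaling (0.00083), equal assigned reads (0.00022) and quantile normalization (3.3e-05). Its member lin-28 fell 6.9-fold and insc fell 5.14-fold. The marker mira was 2.23-fold lower (7.33 ± 3.84, adjusted p = 0.033), a call lost without Ctrl replicate 1 (0.15), without seq&Nicd OE replicate 1 (0.15) or 2 (0.11), and with equal assigned reads (0.15). Levels of pros (7.08 ± 0.786) and elav (6.30 ± 0.239) were without a call (adjusted p = 0.31 and 0.81), and Delta fell 15.4-fold to 4.85 ± 0.651 (6.51-fold without Ctrl replicate 1).

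Other uncalled lists were the enteroendocrine genes (5 of 17 up, 7 down, fry adjusted p = 0.76, with Syt4 up 10.1-fold, or 19.4-fold without Ctrl replicate 3), temporal factors (1 of 5 up, 2 down, 0.55), progenitor markers (1 of 12 up and 4 down, 5 down adjusted over the list alone, 0.51) and digestive genes (1 of 29 up, 1 down, 0.7). Temporal factors and progenitor markers were called down without Ctrl replicate 2 (0.023 and 0.019). Cell cycle genes (8 of 29 up, 1 down, 0.33, with CycE up 14.9-fold) were called up with median scaling (0.026), equal assigned reads (0.043) and by camera with the preset correlation (0.029). Visceral muscle markers (1 of 4 up, 2 down, 0.27, median -0.13 and mean 0.45) were called up with median scaling (0.017, 2 up and 2 down), equal assigned reads (0.0011) and quantile normalization (0.007). The haemocyte, fat body, trachea and glia list (1 of 6 up, 0.35) was called up with equal assigned reads (0.042). Immune effectors were uncalled (1 of 7 down, none adjusted over the list alone, 0.13).

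In all 2832 genes changed, 1092 up and 1740 down, or 38.6% up (limma, Benjamini-Hochberg). Without seq&Nicd OE replicate 1 or 2 the genes down numbered 1147 and 1145, with 925 and 878 up. With only seq&Nicd OE and Ctrl in the fit 1408 changed, 656 up and 752 down. With median scaling 1593 rose and 1538 fell, with quantile normalization 1683 and 1775, with equal assigned reads 2063 and 1006, and with median-of-ratios scaling 1754 and 1525.

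**Figure D3:**
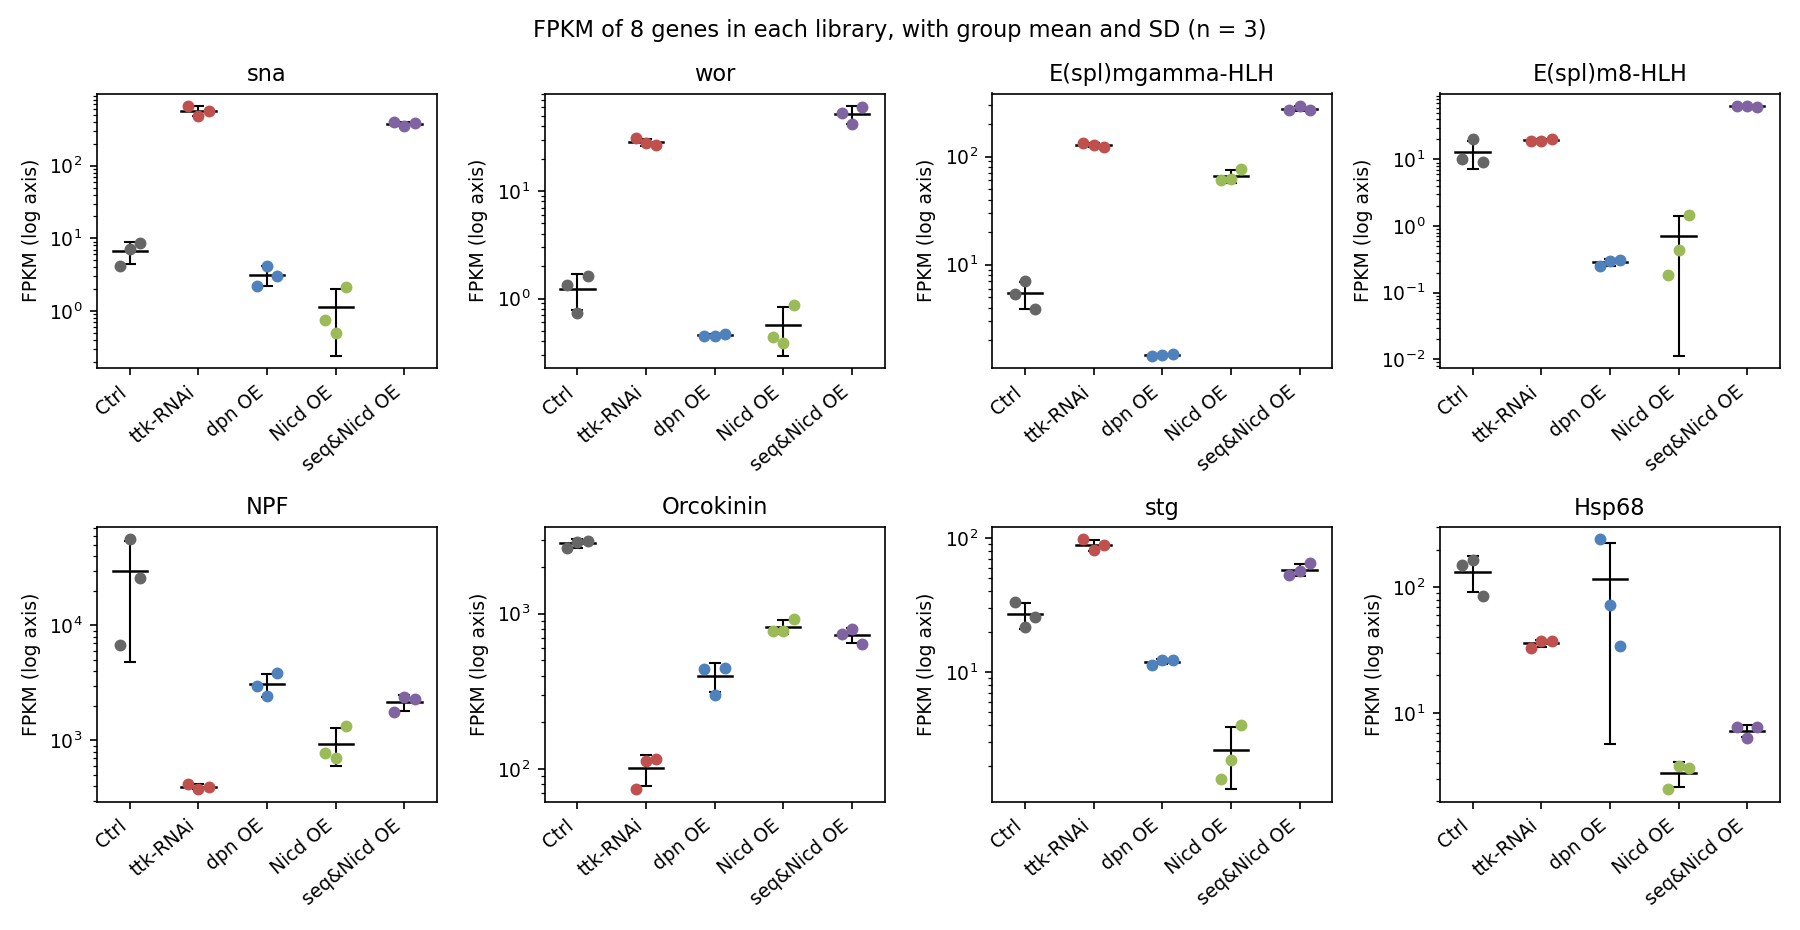
FPKM of 8 genes in each library (points, log axis) with the group mean and SD (n = 3). Libraries labelled ttk-RNAi and seq&Nicd OE held the highest sna and wor, at 571 ± 89.9 and 28.5 ± 2.11 in ttk-RNAi and 378 ± 22.2 and 51.8 ± 9.74 in seq&Nicd OE.

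Libraries labelled seq&Nicd OE were compared with Nicd OE to ask what seq adds to Nicd. The zinc-finger factor genes sna, wor and scrt were higher with seq in the label, sna 336-fold (378 ± 22.2 against 1.12 ± 0.881, 609-fold without Nicd OE replicate 3), wor 91.9-fold (51.8 ± 9.74 against 0.564 ± 0.268) and scrt 57.3-fold. The stathmin gene stai was 100-fold higher. The hormone gene Dh31 rose 92.2-fold, to 263 ± 103 (146-fold without Nicd OE replicate 3). The cell cycle genes stg and CycE rose 22.2-fold and 23.1-fold, to 58.0 ± 6.23 and 9.72 ± 1.57. E(spl)m8-HLH rose 89.3-fold (202-fold without Nicd OE replicate 3) and E(spl)mgamma-HLH 4.21-fold, while E(spl)m3-HLH fell 11.8-fold, from 396 ± 39.1 to 33.5 ± 13.3.

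Further large rises were in lncRNA:CR30009 (501-fold, or 1430-fold without Nicd OE replicate 3), lncRNA:CR44272 (72.2-fold) and dpn (114-fold, or 178-fold without Nicd OE replicate 3). Further large falls were in Jon99Cii (11.7-fold, or 20.2-fold without seq&Nicd OE replicate 3), asRNA:CR44599 (75-fold, interval 38.0 to 174), CG12464 (54.9-fold, interval 28.9 to 120), CG30049 (18.3-fold) and CG34026 (16.3-fold). Of these, Jon99Cii has near-identical copies and asRNA:CR44599 shares 72.2% of its exon bases, so both are uncertain.

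Of 17 neuronal genes 16 rose, 17 adjusted over the list alone (fry adjusted p = 6.4e-07, 0.15 with an estimated correlation), among them Appl (15.1-fold), Cadps (19.7-fold), fne (21.6-fold, or 33.9-fold without Nicd OE replicate 3) and Rdl, a GABA receptor gene (13.7-fold, to 2.70 ± 0.728). The marker elav rose 2.19-fold (adjusted p = 0.0085, or 0.053 without Nicd OE replicate 1). Of 9 proneural factors 6 rose, 7 adjusted over the list alone, and none fell (fry adjusted p = 3.9e-07, 0.2 with an estimated correlation), with mirr 7.89-fold, phyl 16.4-fold and pros 4.43-fold higher (50.6-fold for phyl without Nicd OE replicate 3). Of 20 neuroblast genes 8 rose, 10 adjusted over the list alone, and 1 fell (fry adjusted p = 5.3e-05, 0.71 with an estimated correlation), or 5 rose and 4 fell with median scaling. Among them chinmo rose 72.4-fold (115-fold without Nicd OE replicate 3, 41.9-fold without seq&Nicd OE replicate 3). The markers mira and insc were at 7.33 ± 3.84 and 7.99 ± 2.28 against 3.08 ± 0.12 and 8.50 ± 2.51 (adjusted p = 0.081 and 0.87), and mira was called without seq&Nicd OE replicate 1 (0.048). Of 29 cell cycle genes 21 rose, 25 adjusted over the list alone, and none fell (fry adjusted p = 0.002, 0.64 with an estimated correlation), with the kinase gene polo 12-fold higher (6.96-fold without seq&Nicd OE replicate 3).

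Notch targets rose with 7 of 11 against 4 that fell (fry adjusted p = 4.9e-05, 0.76 with an estimated correlation, 0.061 with median scaling, 4 up and 4 down), E(spl)m7-HLH by 8.46-fold, while E(spl)mbeta-HLH fell 1.97-fold (adjusted p = 0.016, or 0.065 without seq&Nicd OE replicate 3). Enteroendocrine genes rose with 6 of 17, 8 adjusted over the list alone, and none fell (fry adjusted p = 0.0029, 0.71 with an estimated correlation, 0.056 with median scaling, 4 up and 1 down), Syt4 by 11-fold and Syt7 by 5.29-fold. Progenitor markers rose with 3 of 12, 5 adjusted over the list alone (fry adjusted p = 0.0056, 0.83 with an estimated correlation), without a call for Delta (4.85 ± 0.651 against 2.79 ± 2.25, adjusted p = 0.4). The germline list rose with 3 of 4 (fry adjusted p = 0.0025, 0.65 with an estimated correlation), piwi 10.7-fold (6.90-fold without seq&Nicd OE replicate 3). For a gene as low in the compared group as piwi, the filter favours a rise here too. Markers of haemocytes, fat body, trachea and glia (2 of 6 up, fry adjusted p = 0.0029, 0.67 with an estimated correlation) and of visceral muscle (1 of 4 up, 1 up and 1 down adjusted over the list alone, 0.017, 0.98 with an estimated correlation) rose as lists, but not with median scaling (0.056 and 0.32, the latter with 1 up and 1 down).

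Uncalled were temporal factors (1 of 5 up, or 1 up and 2 down with median scaling, fry adjusted p = 0.16, median log2 change -0.16 and mean 0.15) and digestive genes (1 of 29 up, 5 down, 0.33). Mitogen and stress signals were uncalled too (1 of 13 up, or 1 up and 1 down with median scaling, 0.27), as were immune effectors (0 of 7, 0.9, tested up with a median of -0.08 and a mean of -0.11). The same held for heat shock genes (1 of 10 up, or 1 up and 2 down with median scaling, 0.49) and ribosomal proteins (0 of 79, or 2 down with median scaling, 0.97, median 0.03 and mean -0.01). Digestive genes and ribosomal proteins were called down by camera with the preset correlation (0.00028 and 0.0043).

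In all 1611 genes changed, 1295 up and 316 down, or 80.4% up (limma, Benjamini-Hochberg). With median scaling 817 rose and 950 fell, with quantile normalization 1035 and 1124, with equal assigned reads 1285 and 603, and with median-of-ratios scaling 1405 and 638.

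**Figure D4:**
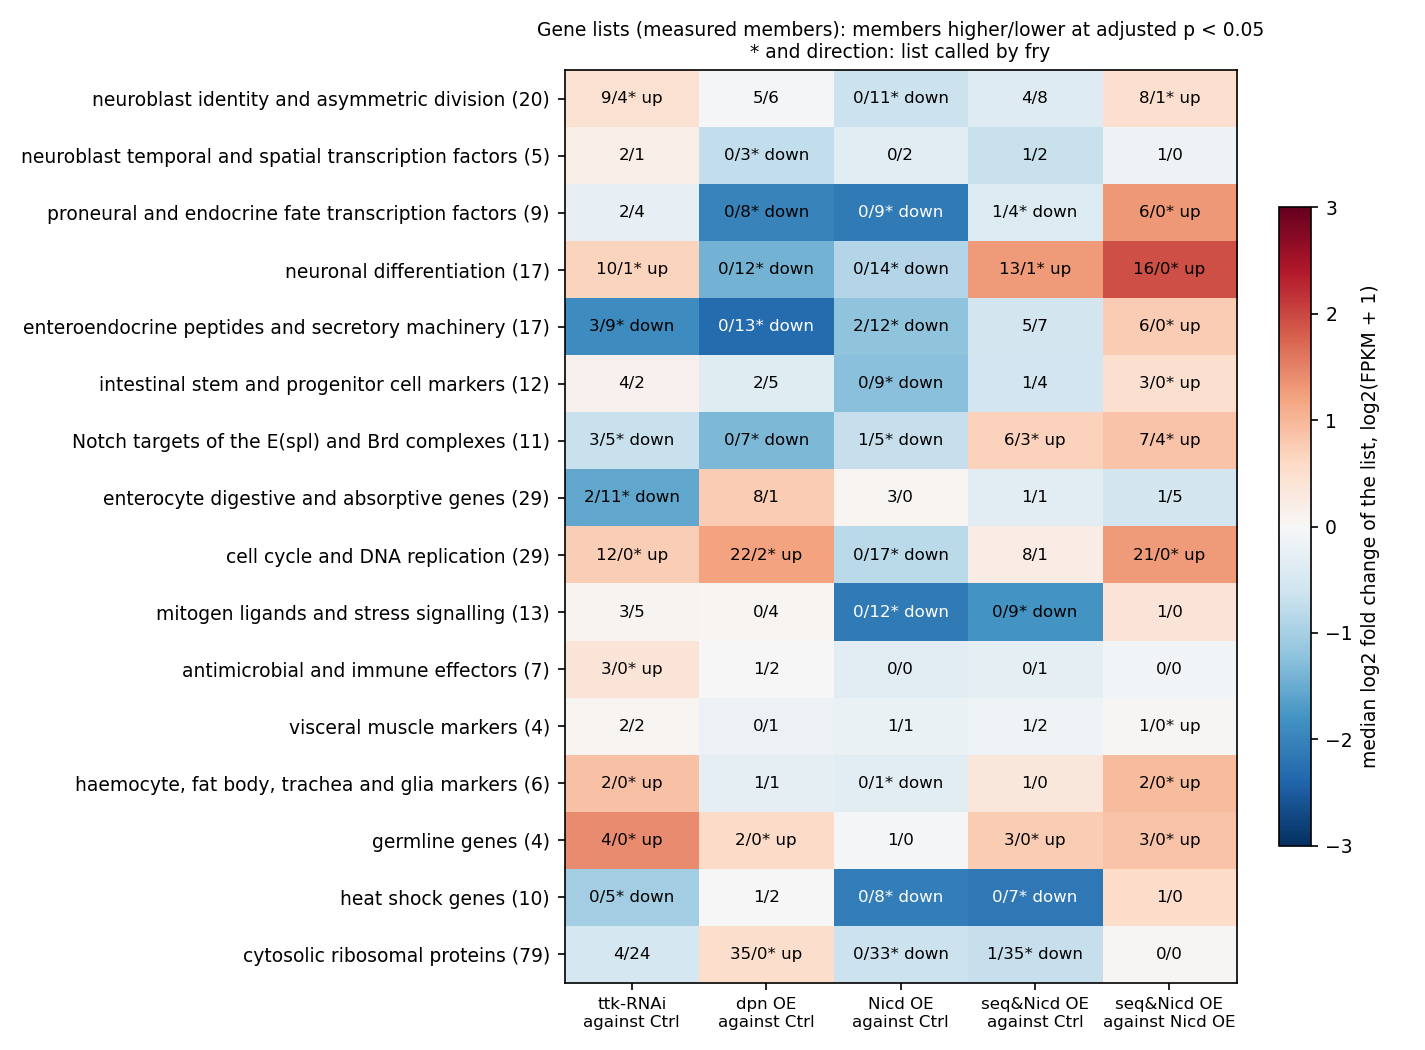
Median log2 change, on log2(FPKM + 1), of each gene list in each comparison (colour), with the number of members higher and lower at an adjusted p under 0.05 and a star and direction where fry called the list. Neuronal genes were called up in ttk-RNAi and seq&Nicd OE and down in dpn OE and Nicd OE against Ctrl, although the calls in ttk-RNAi and Nicd OE were lost with median scaling and all 4 with an estimated correlation (adjusted p = 0.71, 0.33, 0.15 and 0.65 in that order).

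The manipulated groups were also tested against each other, to ask where their effects differed. Between libraries labelled seq&Nicd OE and ttk-RNAi, sna and scrt were not called (log2 difference -0.58 and -0.11, adjusted p = 0.12 and 0.57). There wor was higher in seq&Nicd OE (0.82, adjusted p = 0.0056), and so were Tk (3.81, adjusted p = 5e-06) and E(spl)m8-HLH (1.65, adjusted p = 0.00030). Listericin was lower there by -5.54 (adjusted p = 7.9e-08). Diedel was higher in dpn OE than in ttk-RNAi, Nicd OE and seq&Nicd OE, by 5.87, 6.65 and 6.62 on the log2 scale. Delta was lower in Nicd OE and seq&Nicd OE than in dpn OE (-5.29 and -4.51, adjusted p = 2.2e-06 and 8.5e-06), as were upd2 (-4.86 and -3.57) and Hsp68 (-4.32 and -3.37). Hsp68 was also lower in Nicd OE and seq&Nicd OE than in ttk-RNAi (-3.11 and -2.16, adjusted p = 5.5e-05 and 0.0021). These differences kept their calls or lack of one with median scaling.

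For the lists, adjustment was over the 80 tests of 16 lists in these 5 contrasts, and the calls given here held with median scaling too. A list moved as called on balance, and single members can go the other way. None of the 60 calls of fry in these tests was kept by camera with an estimated correlation, where 15 tests had an unadjusted p under 0.05, and the adjusted p with that correlation follows each group of calls. Neuronal genes were higher in seq&Nicd OE than in ttk-RNAi (fry adjusted p = 0.024) and dpn OE (1.5e-07), lower in dpn OE and Nicd OE than in ttk-RNAi (4.2e-07 and 3.1e-06), and higher in Nicd OE than in dpn OE (0.007), with adjusted p = 0.35, 0.17, 0.17, 0.51 and 0.17 with an estimated correlation. Neuroblast genes were lower on balance in dpn OE (called both ways, median -0.21), Nicd OE and seq&Nicd OE than in ttk-RNAi. Adjusted p was 7.1e-05, 4.9e-07 and 0.00040 by fry, and 0.65, 0.51 and 0.66 by camera. Markers of haemocytes, fat body, trachea and glia were lower there too (1.5e-05, 3e-06 and 9.5e-05, camera 0.17, 0.51 and 0.51). Germline genes were lower than in ttk-RNAi in dpn OE and Nicd OE (0.0011 and 7.1e-05, camera 0.6 and 0.7). The filter favours these falls for genes high only in ttk-RNAi. Visceral muscle markers were lower on balance in dpn OE than in ttk-RNAi (0.047) and higher in seq&Nicd OE than in dpn OE (0.018). Camera gave 0.72 and 0.51. The median log2 differences of these 4 genes were only -0.27 and 0.08, so the calls do not describe each member. Enteroendocrine genes and Notch targets were higher in seq&Nicd OE than in ttk-RNAi (0.00047 and 9.8e-05). Both were higher in seq&Nicd OE (4.1e-05 and 4.6e-07) and Nicd OE (0.0082 and 0.00017) than in dpn OE. Camera gave 0.17, 0.17, 0.21, 0.21, 0.17 and 0.17 in that order. Both were lower on balance in dpn OE than in ttk-RNAi (0.022 and 7.9e-05, camera 0.74 and 0.66), but NPF and E(spl)mbeta-HLH were higher. Proneural factors were lower in dpn OE and Nicd OE than in ttk-RNAi (1.7e-07 and 1.5e-07). They were higher in seq&Nicd OE than in dpn OE (4.9e-07). Camera gave 0.17, 0.38 and 0.17. Temporal factors were lower in dpn OE than in ttk-RNAi (but Eip93F higher), Nicd OE (only mamo called) and seq&Nicd OE. Adjusted p was 0.00026, 0.02 and 0.0021 by fry, and 0.51, 0.21 and 0.38 by camera. Progenitor markers were lower in dpn OE (called both ways, Delta higher), Nicd OE and seq&Nicd OE than in ttk-RNAi (0.015, 9.5e-05 and 0.017). Camera gave 0.74, 0.7 and 0.74. Immune effectors were lower and ribosomal proteins higher in dpn OE than in ttk-RNAi (0.0016 and 0.0014, camera 0.51 and 0.66). Mitogen and stress genes were lower in Nicd OE and seq&Nicd OE than in ttk-RNAi (7.9e-05 and 0.00026) and dpn OE (0.00029 and 0.0021), with adjusted p = 0.63, 0.51, 0.75 and 0.85 with an estimated correlation. Heat shock genes were lower in these 2 groups than in dpn OE (0.00027 and 0.00077), and cell cycle genes lower in Nicd OE than in ttk-RNAi (0.00015) and dpn OE (0.00013), with adjusted p = 0.74, 0.74, 0.66 and 0.70 with an estimated correlation. Digestive genes were higher in dpn OE, Nicd OE and seq&Nicd OE than in ttk-RNAi (0.00029, 0.0027 and 0.02). Camera gave 0.51, 0.17 and 0.17.

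The numbers of genes higher and lower were 3181 and 1888 in dpn OE against ttk-RNAi, 606 and 4446 in Nicd OE against ttk-RNAi, and 622 and 3072 in seq&Nicd OE against ttk-RNAi. They were 575 and 4930 in Nicd OE against dpn OE, and 1288 and 4535 in seq&Nicd OE against dpn OE. With median scaling the same pairs gave 2575 and 2582, 2547 and 1884, 1751 and 1577, 2946 and 1824, and 2586 and 2247. The median log2 differences of all genes were 0.31, -0.67, -0.42, -0.88 and -0.72 in the same order.

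Overlaps between comparisons against the same Ctrl libraries were counted last. Libraries labelled ttk-RNAi and seq&Nicd OE shared 1553 genes changed the same way, 839 up and 714 down, with 335 and 238 for independent lists, and 114 changed the opposite way against 683. Those labelled Nicd OE and seq&Nicd OE shared 1639, 209 up and 1430 down against 55 and 596, with 143 opposite against 462. In ttk-RNAi and dpn OE 1073 rose and 345 fell in both against 1122 and 140, with 578 opposite against 815, and in ttk-RNAi and Nicd OE 193 and 732 against 128 and 384, with 520 opposite against 919. In dpn OE and Nicd OE 230 rose and 654 fell in both against 185 and 352, with 1028 opposite against 1305, and in dpn OE and seq&Nicd OE 322 and 391 against 487 and 218, with 732 opposite against 912. Changes in ttk-RNAi and seq&Nicd OE had a Spearman correlation of 0.60 across genes and a covariance of 0.63, and those in Nicd OE and seq&Nicd OE 0.67 and 0.40. The other 4 pairs had correlations of 0.11, 0.33, 0.25 and 0.14 and covariances of 0.12, 0.25, 0.22 and 0.09 in the order above. Unchanged groups, simulated against simulated controls with the spread per gene pooled over all groups, gave 0 shared genes, a correlation of 0.47 and a covariance of 0.05. With the libraries of Nicd OE and seq&Nicd OE also correlated by replicate number as measured, the simulation of that pair gave at most 1 shared gene, a correlation of 0.60 and a covariance of 0.06. The 3 controls are too few to split, so part of the excess may come from the shared controls, and genes are not independent replicates. The real Ctrl libraries were less alike (correlations of 0.91 to 0.97) than those of the other groups, so the simulations may understate that part. With median scaling ttk-RNAi and seq&Nicd OE shared 973 up and 962 down against 378 and 414, Nicd OE and seq&Nicd OE 778 and 795 against 304 and 215, and ttk-RNAi and dpn OE 488 and 869 against 438 and 695. In the same order as above, the other 3 pairs then shared 609 and 625 against 372 and 309, 548 and 578 against 352 and 361, and 422 and 692 against 358 and 484.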

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

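Chosen after the results were seen were equal assigned reads, median-of-ratios scaling, median scaling of lists, overlaps and pairs of manipulated groups, camera for those pairs, the method of the array weights, the simulation correlated by replicate number and the tests by splits, and the other alternatives were chosen before the data were examined. Of 3473 recomputed values of 205 pairs of a named gene and a contrast, 3404 kept their direction and side of the threshold, 26 lost the call, 43 gained one and 0 reversed. Of the 80 list tests 53 were the same with median scaling, 67 with equal assigned reads and 63 with quantile normalization, as were 54 of 64 without Ctrl replicate 2. The germline list in dpn OE against Ctrl turned down with median scaling (adjusted p = 0.63), and the ribosomal list in Nicd OE against Ctrl turned up with equal assigned reads (0.97). The cause was not tested for any change of value given here, apart from the smaller number of genes or libraries that a filter, a minimum change or a left-out library brings.

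With FPKM of at least 5 in 3 libraries, 2329 genes changed in ttk-RNAi, 3079 in dpn OE and 1792 in seq&Nicd OE against Ctrl, and 912 in seq&Nicd OE against Nicd OE. A log2 change of at least 1 left 2160, 2724, 1531 and 1479 genes in ttk-RNAi, dpn OE, Nicd OE and seq&Nicd OE against Ctrl, and 921 in seq&Nicd OE against Nicd OE. With only 2 groups in the fit, 3188, 3884, 1512 and 1408 changed in ttk-RNAi, dpn OE, Nicd OE and seq&Nicd OE against Ctrl. Array weights, from 0.09 for Ctrl replicate 2 to 8.04 for ttk-RNAi replicate 3, gave 4990 in Nicd OE against Ctrl and 3312 in seq&Nicd OE against Nicd OE. With a log2 change of at least 1 in both, overlaps were 581 (ttk-RNAi and dpn OE), 379 (ttk-RNAi and Nicd OE), 752 (ttk-RNAi and seq&Nicd OE), 386 (dpn OE and Nicd OE), 297 (dpn OE and seq&Nicd OE) and 720 (Nicd OE and seq&Nicd OE). That of dpn OE and seq&Nicd OE was 1130 with quantile normalization and 1114 with median scaling. Lists called in Nicd OE were 7 with quantile normalization, 7 with median scaling and 6 with equal assigned reads, and in seq&Nicd OE against Nicd OE 6 with median scaling. With camera at a preset correlation 5 were called in ttk-RNAi, 1 up and 4 down, and 5 in seq&Nicd OE against Nicd OE, 3 up and 2 down, where fry called 6 up and 4 down, and 10 up and 0 down. With an estimated correlation 0, 1, 0, 0 and 0 were called in ttk-RNAi, dpn OE, Nicd OE, seq&Nicd OE and seq&Nicd OE against Nicd OE, and at an unadjusted p under 0.05 this test had 0, 5, 1, 1 and 2.

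Between manipulated groups, 53 of 80 list tests and 83 of 105 gene tests were the same with median scaling, while 11 and 5 reversed. Camera with an estimated correlation kept 0 of the 60 calls of fry there. In Nicd OE against ttk-RNAi the temporal (0.076), Notch target (0.0021) and visceral muscle (0.0031) lists turned up, as did the germline list in seq&Nicd OE against ttk-RNAi (0.72). In Nicd OE against dpn OE the neuroblast (0.03), proneural (0.00032), immune (0.011), visceral muscle (6e-06), haemocyte (0.0061) and germline (0.00019) lists turned up, and in seq&Nicd OE against dpn OE the progenitor list (0.0013). The log2 difference of Diedel in Nicd OE against ttk-RNAi became 0.0, those of N, elav and sna in Nicd OE against dpn OE 0.23, 0.28 and 0.03, and that of ttk in seq&Nicd OE against dpn OE 0.72 (adjusted p = 0.045).

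Leaving out each library in turn gave 2650 to 3838 genes in ttk-RNAi, 3764 to 4857 in dpn OE, 2151 to 4068 in Nicd OE and 2023 to 3405 in seq&Nicd OE against Ctrl, and 1188 to 1887 in seq&Nicd OE against Nicd OE. The lowest count in Nicd OE, 2151, came without Nicd OE replicate 1. Lists called ranged over 8 to 11, 7 to 9, 8 to 13, 6 to 8 and 9 to 10 in the same order. Overlaps ranged over 1078 to 1783 (ttk-RNAi and dpn OE), 715 to 1230 (ttk-RNAi and Nicd OE), 1228 to 1773 (ttk-RNAi and seq&Nicd OE), 660 to 1050 (dpn OE and Nicd OE), 541 to 873 (dpn OE and seq&Nicd OE) and 1128 to 2246 (Nicd OE and seq&Nicd OE).

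With the replicate block, 3615, 4679, 3176, 2784 and 1599 genes changed in ttk-RNAi, dpn OE, Nicd OE and seq&Nicd OE against Ctrl and in seq&Nicd OE against Nicd OE, and 10, 7, 12, 7 and 10 lists were called. Only the last contrast has numbers that were read as a possible pairing, and the block changed no call of a list or named gene there. The block fitted an effect per replicate number common to all 5 groups. It did not model the pairing of these 6 libraries alone, so the unchanged calls do not test that pairing. Elsewhere the numbers are only shared: the ribosomal list in dpn OE lost its call (0.089), the temporal list in Nicd OE gained one (0.031), and Delta and N in dpn OE gained one (0.048 and 0.047). Of the 6 libraries of a pair of groups, at most 4 correlated best with their own number, in Nicd OE and seq&Nicd OE. Depth sets the lowest value that can be read, as 3 reads in a gene of 1 kb were worth 0.054 to 0.122 FPKM.

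Only 10 splits of 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split gave 3638, 4686, 3227, 2832 and 1611 genes in the order above (limma) and the highest of the others 0, 13, 1367, 621 and 0. For lists (fry) the real split gave 10, 8, 11, 7 and 10 and the highest other 0, 1, 5, 2 and 2. In each case the 1 split with a count as large was the real one.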

Other observations

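The tests of explanations in this part were chosen after the results were seen, and the genes of the first 2 paragraphs and of the last after their values were seen.

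Of the cell death genes rpr, skl, grim and hid, the first 3 were higher in libraries labelled ttk-RNAi and seq&Nicd OE than in Ctrl and hid was lower. The cell death activator rpr was at 2.07 ± 0.604 FPKM in Ctrl (SD, n = 3 in each group), 114 ± 22.5 in ttk-RNAi and 37.7 ± 5.42 in seq&Nicd OE, 55.1-fold and 18.2-fold higher (limma, adjusted p = 1.27e-10 and 2.48e-08). Its relative skl rose from 0.441 ± 0.304 to 73.0 ± 5.94 and 35.8 ± 5.61, and grim, which shares 75.9% of its exon bases with other genes and is uncertain, rose 79.5-fold and 29.4-fold. The related gene hid fell, from 4.50 ± 1.46 to 0.750 ± 0.118 and 1.19 ± 0.342 (adjusted p = 0.000285 and 0.00246). In dpn OE rpr fell to 0.0678 ± 0.0299 (adjusted p = 0.000142), and in Nicd OE it was at 2.45 ± 1.11 (adjusted p = 0.679). The other 3 were not called in these groups: skl was at 0.0144 ± 0.0250 in dpn OE and 0.271 ± 0.183 in Nicd OE (adjusted p = 0.055 and 0.538), grim was listed at 0 in each dpn OE library and at 0.0358 ± 0.0450 in Nicd OE against 0.227 ± 0.0503 in Ctrl (0.236 and 0.365), and hid was at 6.66 ± 2.89 and 4.38 ± 1.41 (0.205 and 0.952).

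A further 5 genes are given from libraries with the same labels, and as picked genes they stand for no larger set. The glutamate transporter gene Eaat1 rose 344-fold to 56.5 ± 1.35 in ttk-RNAi and 70.7-fold to 11.6 ± 2.47 in seq&Nicd OE. The axon guidance receptor gene robo3 reached 23.0 ± 0.505 and 5.15 ± 2.76, the cell surface gene dpr11 11.0 ± 0.663 and 11.8 ± 2.07, and the homeobox gene ind 33.2-fold and 29.3-fold its Ctrl level (66.6-fold and 58.8-fold without Ctrl replicate 2). stai, named above in seq&Nicd OE, also rose in ttk-RNAi, 82.4-fold to 282 ± 59.9.

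Of the manipulated genes, ttk was higher in libraries labelled ttk-RNAi than in Ctrl, dpn rose 2.57-fold in dpn OE (adjusted p = 0.0082, or 0.053 with median scaling) but to no more than 6.09 ± 1.30 FPKM, seq was listed at 0 throughout, and N was lower in both groups labelled with Nicd. For ttk, scaling between libraries is argued against as the whole cause by a lowest log2 change of 1.44 over 4 other scalings, and a swap of 1 library by a lowest ttk-RNAi library at 87.05 FPKM against 43.57 for the highest of the other 12. For N, uncounted reads over exons shared with other genes are argued against, since 0 percent of its exon bases are shared, whereas for seq this is a candidate explanation, as 96.9% of protein-coding genes lying wholly within others (98.4% of those within genes of the opposite strand only) were listed at 0 in each library, against 2.9% of those sharing none. For dpn, with 17.0% of its coding bases outside an antisense gene, loss of transgene reads on shared bases stays open, because the construct is not in the labels. Reads from the RNAi construct, a rise of the endogenous ttk transcript and a label that is wrong for the whole group cannot be told apart from 1 value per gene (log2 change 1.89), and which part of N the transgene carries was not tested.

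Enteroendocrine genes were lower in libraries labelled ttk-RNAi, dpn OE and Nicd OE, in the last not with median scaling (adjusted p = 0.073), equal assigned reads (0.057) or quantile normalization (0.052). With an estimated correlation no call was kept (adjusted p = 0.58, 0.18 and 0.71), and for the calls of fry a control library apart from the others is argued against as the cause, since without Ctrl replicate 2 the highest adjusted p of the 3 was 0.0035. Fewer enteroendocrine cells among the GFP-sorted cells stay open in dpn OE, where the abundant peptide gene Orcokinin was at 396 ± 84.4 FPKM against 2831 ± 173.8: that 0 of the 17 genes were higher relative to the median gene decides nothing, as none was higher before that scaling, which lowers these libraries. With 2 genes higher in ttk-RNAi and 2 in Nicd OE they stay open there too, and in seq&Nicd OE, where 5 were higher, the list was not called (0.76), so that the test for fewer enteroendocrine cells says nothing. Each of the 17 genes had a mean of at least 1 FPKM in Ctrl and 0 are on another list, and an effect of the labelled genes within cells stays open, as untested.

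Heat shock genes were lower in libraries labelled Nicd OE and seq&Nicd OE, and also in ttk-RNAi (adjusted p = 0.023), with adjusted p = 0.62, 0.58 and 0.59 with an estimated correlation. For both groups labelled with Nicd, a smaller share of reads assigned to genes is argued against as the whole cause by a highest adjusted p of 0.0037 with equal assigned reads, and a control library apart from the others by 0.0027 without Ctrl replicate 2. A sorting or library batch shared by both cannot be told apart from an effect of Nicd, because the labels give no batch and at most 48.9% of reads were assigned to genes there against at least 56.4% in the other libraries. An effect of Nicd itself stays open, as untested.

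In both Nicd OE and seq&Nicd OE, replicate 3 differed from both other replicates by more than 2 log2 units in 7 genes, while replicates 1 of both groups, replicates 2 of both and each pair with unlike numbers shared 0 such genes. Nap1 was at 0.272, 0.305 and 26.5 FPKM in Nicd OE and at 0.180, 0.179 and 19.1 in seq&Nicd OE, in order of replicate number, against 22.6 to 40.4 in the libraries of Ctrl and ttk-RNAi and 0.220 to 0.433 in those of dpn OE, so that replicates 1 and 2 were the ones far from Ctrl. 2SrRNA:CR45864 was at 105, 81.6 and 4.89 in Nicd OE and at 334.5, 274.3 and 4.82 in seq&Nicd OE, against 1.03 to 10.7 in the other 9 libraries.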
